A study of Mus musculus with 14 samples.

How the data were processed

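RNA from mouse fibroblasts lacking the phosphatidylserine receptor gene Ptdsr (current symbol Jmjd6) was compared with RNA from wild-type fibroblasts on 14 two-colour cDNA microarrays. Each array carried knockout RNA in one dye and wild-type RNA in the other. Per the labels, the knockout was in Cy5 on 7 arrays (replicates 1, 3, 4, 7, 8, 9 and 13) and in Cy3 on 7 arrays (replicates 2, 5, 6, 10, 11, 12 and 14). The series design names 2 cultures, but no label ties an array to a culture. P-values therefore measured the spread between arrays only, part of which may be technical. Per the labels' protocols, total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5. The same protocol text speaks of organs and of a reference pool from control animals, while the channel labels name wild-type fibroblasts, and the channel labels were followed here. The wild-type RNA served as 1 control sample whose own spread was not measured. The scanner, background correction and normalization are not given in the sources used here.

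The authors deposited log2 ratios of the channels for 20355 probes on each array. The base of the logarithm was read from the values. The most frequent ratios were ratios of small whole numbers, and their steps fit base 2. All such steps of an array were displaced by a single constant, so these ratios carried 1 shift per array. Whether the other ratios carried a correction that depended on intensity was not tested. The arrays' medians as deposited lay between -0.334 and 0.245, so the arrays were not centred on a common median. Each array also held 1 repeated extreme, which lay 16.6 log2 units (a ratio of 100000) from its 1:1 step. This extreme filled between 91 and 315 cells per array and was read as a code for a zero denominator.

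The direction of the ratios is likely, but it is not stated in the labels. The coded extreme was positive on all 7 arrays with the knockout in Cy5 and negative on all 7 arrays with the knockout in Cy3. If the scanner ratio was formed as Cy5 over Cy3, the authors had already turned the dye-swapped arrays, and the deposited values were knockout over wild type. They were used in that direction. If the ratio had been formed as Cy3 over Cy5, every sign given here would turn. If it had been formed as knockout over wild type and then turned to Cy5 over Cy3, the dye-swapped arrays would still need turning. The plan made before the data were examined was to leave the values as deposited only if arrays of opposite dye correlated above 0. That rule gave no single answer. Over all probes, 25 of the 49 pairs of opposite dye had a rank correlation above 0, with a median of 0.00049, and over the 2677 best measured probes 36 of 49 did, with a median of 0.040. Within replicates 1 to 6 and within replicates 7 to 12, all 18 such pairs lay below 0 over all probes (-0.229 to -0.018), where the rule goes against the direction used here. Over the best measured probes, 12 of the 18 lay above 0 (median 0.042). These ranges of numbers are no labelled groups and were chosen after the values had been seen. The coded extremes were used in place of the rule after the values had been seen, and the turned reading was run as an alternative. In the model described below, turning exchanges the mean and the dye term, so the alternative repeats the test of the dye term. Arrays of the same dye had a lowest Pearson correlation of -0.197 over all probes.

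Coded extremes were set to missing, as the ratio of the opposite case (a zero numerator) was already missing. Each array was then centred on its median. Probes with values on at least 10 arrays, and on at least 4 of each dye orientation, were tested. This left 18503 probes, of which 6134 had a value on all 14 arrays. Between 649 and 6875 values per array were missing, with replicates 1 and 2 at 5805 and 6875 and the other arrays at 2452 or fewer. The deposited ratios carry no spot intensity, and how far missing values limit the precision of an array was not measured. As a stand-in for dim spots, ratios of whole numbers up to 10, matched within 0.0011 log2 units, were counted. They made up between 13.4% and 31.4% of an array's values, against 1.86% to 3.29% on a shifted grid.

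Tests were run with limma 3.58.1 in R 4.3.3. The model held an intercept, tested against 0 as the mean log2 ratio, and a dye term coded +1 and -1. P-values came from lmFit and eBayes with Benjamini-Hochberg adjustment, and a probe was called at an adjusted p below 0.05. A second count required a change of at least 1.5-fold. The model was tested on simulated data with the real missing values and independent normal noise on each array. The real arrays were not independent, so the rates and false calls given here may not hold for them. Of probes shifted by 1 log2 unit 37.5% were recovered, of probes shifted by 1.5 units 65%, and of probes shifted by 0.5 units 3.75%, among 18503 probes tested, with 4 false calls. Among probes with a residual SD under 0.5, all 17 shifted by 1 log2 unit were recovered.

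Probe names came from the platform annotation and were checked through gene numbers against a RefSeq table. Start positions from that table served to pick the genes lying between the list members inside the histocompatibility complex. A single symbol was given for 14030 probes, several for 5 and none for 6320, and 41 annotated probes had no match by gene number. For gene lists, probes of a gene were averaged on each array, which gave 9270 genes. The 32 lists were fixed at the same stage, and 31 held at least 5 measured genes. The list of sex-linked genes, with 4, was not tested. Lists were tested with limma's cameraPR at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry cannot take missing values, so both ran on the 4624 genes with values on all arrays, where 29 lists remained.

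The genes named were Jmjd6, up to 14 called genes in each direction with the same sign on all but at most 1 array and in both dye orientations, and up to 4 called members of each list. Where a list had no called member, up to 2 members with the smallest p were eligible as values. Other genes are marked as chosen after their values were seen. Alternatives fixed in advance covered centring, scaling, the dye term, the filter on missing values, array weights, robust and trended eBayes, each dye orientation alone, each array left out and other set tests. Alternatives added after seeing the data covered the direction of the ratios, the coded extremes, dim spots (3 settings), position on the array, the removal of arrays 1 and 2, and a block for replicates 1 to 6, 7 to 12 and 13 to 14. These ranges hold both dye orientations equally. All 12 pairs of the same dye within the first 2 ranges lay above 0 over all probes (0.136 to 0.334), against 9 of 30 elsewhere, so the 14 arrays were not independent. Blocks were random (duplicateCorrelation, consensus correlation -0.021 by range and 0.224 by range and dye) or fixed. No columns were identical, and no value column was left out.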

Results

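The data consisted of 14 arrays, each comparing RNA of Ptdsr-deficient mouse fibroblasts with wild-type fibroblast RNA. Ptdsr (Jmjd6) was first described as a receptor for phosphatidylserine, the lipid that marks apoptotic cells for uptake, and encodes a nuclear JmjC-domain protein. The knockout was in Cy5 on 7 arrays and in Cy3 on the other 7, and between 13165 and 19615 of 20355 probes had a usable log2 ratio on an array. All values below are log2 ratios of knockout over wild type, and this direction is likely rather than stated. It rests on the coded extremes in the deposited values, and correlations between arrays of opposite dye did not bear it out over all probes. No genome build is named in the sources, so genes are given by symbol without positions.

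The Jmjd6 probe was the first check of the labels. Its mean log2 ratio was -0.51 ± 1.14 (SD, n = 14), and it was lower in the knockout on 12 of 14 arrays. It did not pass the test (limma, adjusted p = 0.895, unadjusted p = 0.0947). With the knockout in Cy5 the mean was -0.81 ± 0.45 (SD, n = 7), and with the knockout in Cy3 it was -0.21 ± 1.55 (SD, n = 7). Replicate 2 alone stood at 2.92, and replicate 6 was the other array above 0, at 0.46. A second Jmjd6 probe had values on 5 arrays, between -1.65 and 1.09, and was not tested. Whether either cDNA probe lies in the deleted part of the gene is not given in the sources used here, and a probe outside it checks nothing.

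The comparison of knockout with wild-type fibroblasts asked which transcripts differ without Ptdsr. Among 18503 probes, 6 differed, all of them lower in the knockout and all by at least 1.5-fold, and 0 were higher. Mmp13, which encodes collagenase 3, had the lowest mean among them at -1.64 ± 0.59 (SD, n = 14), a 3.12-fold reduction, with values from -2.78 to -0.97 between arrays. H2-K1, a classical class I histocompatibility gene, lay at -1.5 ± 0.55 (SD, n = 14), and Lyz2, the lysozyme of macrophages, at -1.47 ± 0.80 (SD, n = 12), with values from -3.04 to -0.47. The other called genes were Lpl (lipoprotein lipase) and the interferon-inducible genes Ifi27 and Ifi205.

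Each of these 6 probes was lower on every array that measured it, in both dye orientations. The adjusted p from limma was 0.000827 for Mmp13 and for H2-K1, 0.00192 for Ifi27 and 0.00446 for Lpl. It was 0.0315 for Ifi205 and 0.0454 for Lyz2, the closest to the threshold. Leaving out 1 array ended the Ifi205 call for 7 of the 14 arrays and the Lyz2 call for 9 (adjusted p up to 0.113 and 0.126). With arrays of the same number range (replicates 1 to 6, 7 to 12 or 13 to 14) and dye as a random block, Mmp13, H2-K1, Ifi27 and Lpl stayed called (adjusted p up to 0.0177), and Ifi205 and Lyz2 did not (0.135 each). Lpl had a mean of -1.20 ± 0.49 (SD, n = 14), Ifi27 of -1.01 ± 0.32 (SD, n = 14) and Ifi205 of -0.82 ± 0.28 (SD, n = 13). Mmp13 had nearly equal means in both dye orientations, at -1.63 with the knockout in Cy5 and -1.65 with the knockout in Cy3. H2-K1 stood at -1.32 and -1.68, and Lyz2 at -1.18 and -1.76. Further probes of Lpl gave -0.97 and -0.85, each lower on 12 of 13 arrays with an adjusted p of 0.408. A second Lyz2 probe gave -1.55 and was lower on 13 of 14 arrays, with an adjusted p of 0.0595. Cross-hybridisation within gene families was not measured, so the H2-K1, Lyz2 and Ifi205 values may include related genes.

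**Figure D1:**
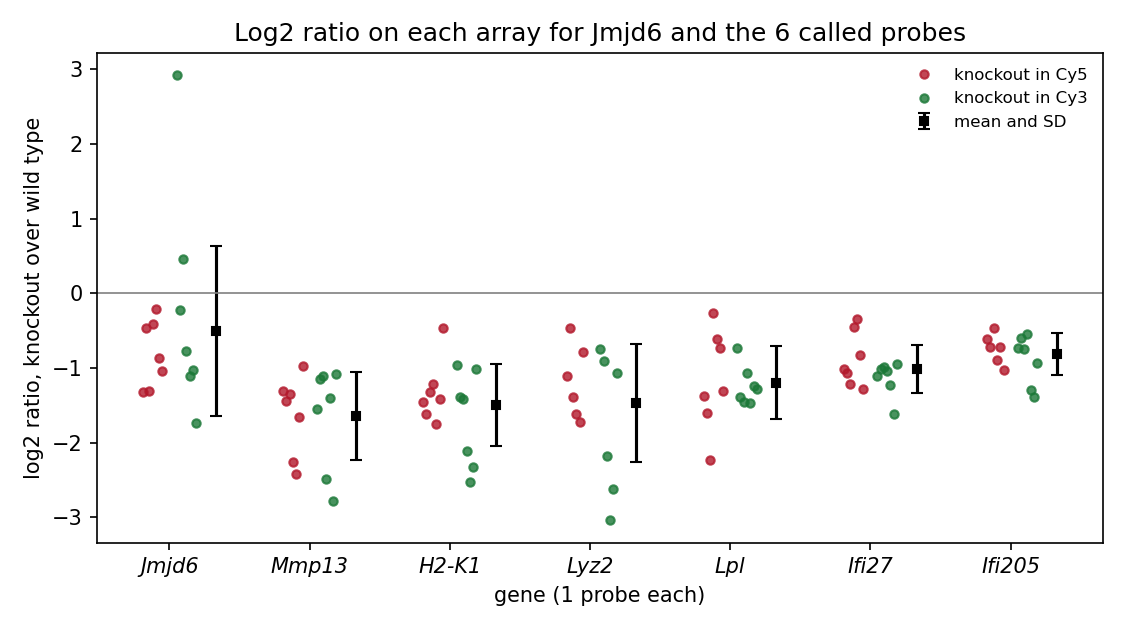
Log2 ratio of knockout over wild type (vertical axis) on each array for the Jmjd6 probe and the 6 called probes (horizontal axis), with red points for the knockout in Cy5, green points for the knockout in Cy3, and black squares with bars for mean and SD. The points of the 6 called probes lie below 0 on every array that measured them, while Jmjd6 has 2 arrays above 0, the higher at 2.92.

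At an unadjusted p below 0.05, 935 probes differed, 425 higher and 510 lower, against a nominal 5% of 925. Other sign patterns of the arrays gave a median of 730 (437 to 1621). When probes were averaged per gene, 8 of 9270 genes were called, all lower. The count was 5 with arrays of the same number range and dye as a random block, 13 (1 higher) with number ranges as a fixed block, 0 with robust and trended eBayes or either dye orientation alone, and 4, none of them shared, with the Cy3 arrays turned. The 8 were the genes of the 6 probes together with Ifitm3 at -0.70 ± 0.34 (SD, n = 14, adjusted p = 0.0203) and Psmb8 at -0.73 ± 0.34 (SD, n = 14, adjusted p = 0.0203). Each has 1 probe, and the same values did not pass among all probes (adjusted p = 0.0559 each). Leaving out single arrays ended the Ifitm3 call for replicates 3, 4, 8, 10 and 14 and the Psmb8 call for 3, 4, 5, 6, 8, 9 and 14 (adjusted p up to 0.067), and the block of number range and dye ended both (0.0735 and 0.157). Ifitm3 restricts virus entry, and Psmb8 is a subunit of the immunoproteasome. Robust and trended eBayes called 0 probes with the means unchanged (adjusted p = 0.382 for Mmp13 and H2-K1). Its trend follows the mean log2 ratio, the quantity tested, and a trend on the share of small whole-number ratios called 12. The 7 arrays of either dye orientation alone called 0. If the dye-swapped arrays had in fact not been turned before deposit, the 6 probes would mark a constant dye effect. Turning those arrays left 1 called probe, Nr4a3, and none of the 6. This setting exchanges the mean and the dye term of the model, so it is the dye test given below and no separate test.

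Of the 31 gene lists tested, 4 passed, 3 lower and 1 higher. Among 100 drawn sign patterns of the arrays, 28 other than the real one also called at least 1 list. Interferon response and antigen presentation genes were lower, with a mean log2 ratio of -0.32 over 30 measured members (adjusted p = 5.42e-10). Of these members 4 fell and 0 rose over all genes tested, while 26 did not pass, and 8 were lower when adjusted over the list alone. H2-K1, Ifi27, Ifitm3 and Psmb8 were the 4 called members. B2m, the invariant chain of class I molecules, stood at -0.74 ± 0.44 (SD, n = 14) and the peptide transporter gene Tap1 at -0.50 ± 0.35 (SD, n = 14), with adjusted p of 0.0747 and 0.417 over all genes. Bst2 (-0.78) and Ifi35 (-0.31) completed the 8. The members were not uniform, as Irf1 had a mean of 0.33 and Rsad2 of -0.04, each within the spread between arrays. B2m, Tap1, Bst2, Ifi35, Irf1 and Rsad2 were chosen after their values were seen. Camera with an estimated correlation and fry could use only the 12 members with values on all arrays, whose mean was -0.62. On these 12 the adjusted p was 0.000257 and 2.74e-06, and no other list passed with an estimated correlation.

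**Figure D2:**
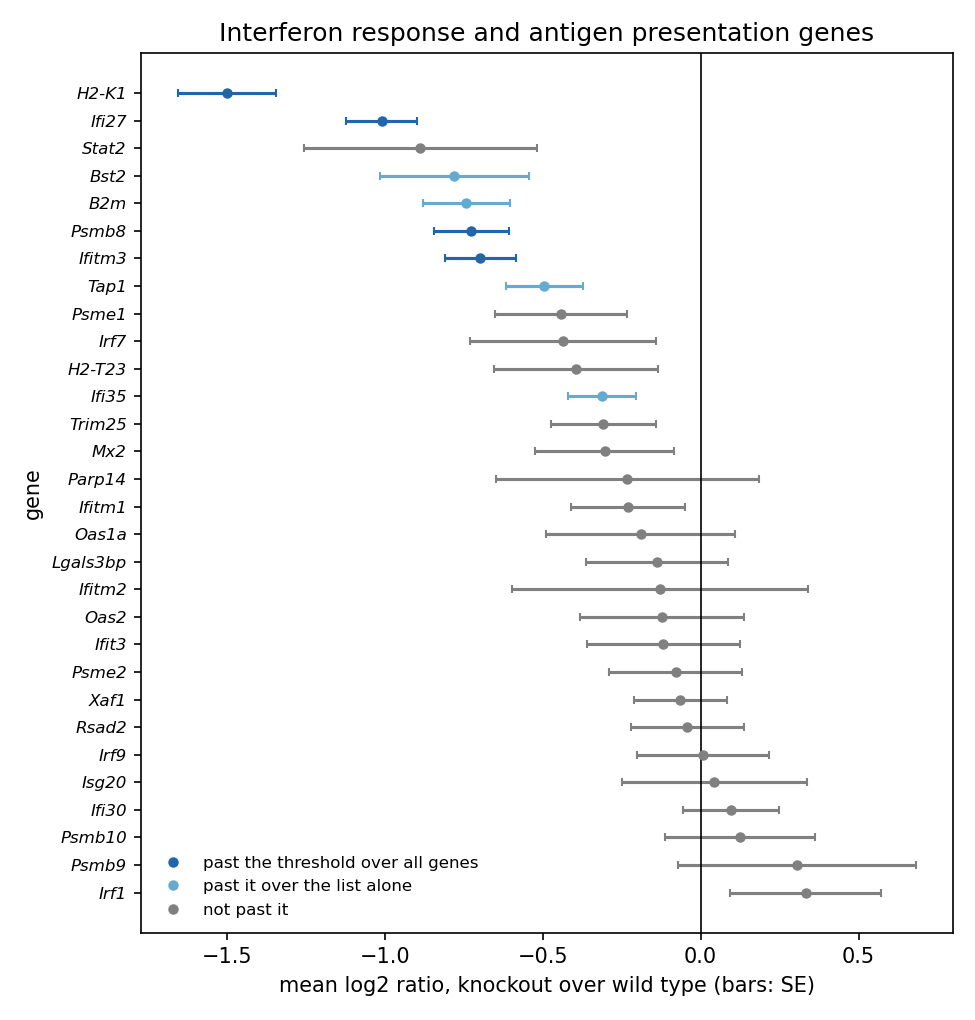
Mean log2 ratio of knockout over wild type with its standard error (horizontal axis) for each of the 30 measured interferon response and antigen presentation genes (vertical axis), coloured by whether the gene passed over all genes, over the list alone, or not. Means run from -1.5 for H2-K1 to 0.33 for Irf1, and 24 of 30 lie below 0.

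The macrophage and leukocyte markers, fixed as a check for other cells in the cultures, had a mean of -0.16 over 28 members and did not pass (adjusted p = 0.127). Of these 28, Lyz2 fell at a gene mean of -1.62 ± 0.96 (SD, n = 14), and 27 did not pass. Cd68 stood at -0.52 ± 0.55 (SD, n = 13, adjusted p = 0.751), a value given after it was seen.

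Matrix proteases and their inhibitors were lower on average, with a mean of -0.18 and a median of -0.07 over 27 members (adjusted p = 0.0422). The list did not pass with an estimated correlation (adjusted p = 0.319) or with the block of number range and dye (0.0520), and fry gave an adjusted p of 0.0463. Mmp13 was the called member, 26 did not pass, and 2 were lower when adjusted over the list alone. The second, chosen after its value was seen, was the stromelysin gene Mmp3, at -1.78 ± 1.53 (SD, n = 14) and lower on 14 of 14 arrays, with an adjusted p of 0.222 over all genes. Its values ran from -4.84 to -0.24 between arrays, and with number ranges as a fixed block, which takes the spread between ranges out of the error, its probe was called (adjusted p = 0.00537). It was not called with number ranges, or number range and dye, as a random block. Cytokine and chemokine genes had a mean of -0.24 over 21 members (adjusted p = 0.0422). The list did not pass with an estimated correlation (adjusted p = 0.992), with fry (0.967), with values required on all arrays (0.833) or with the block of number range and dye (0.0520). By limma 0 of the 21 were called, also when adjusted over the list alone, with 4 lower and 0 higher at an unadjusted p below 0.05. Its members with the smallest p were Ccl5 at -1.02 ± 1.08 (SD, n = 13) and Ccl8 at -0.65 ± 0.92 (SD, n = 13). The Ccl5 probe was called with number ranges as a fixed block (adjusted p = 0.00844), but not with either random block.

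Ribosomal protein genes were higher on average, at a mean of 0.083 over 59 members (adjusted p = 0.0168), with 42 above 0 and 17 below. The mean was 0.155 with the knockout in Cy5 and 0.013 with it in Cy3, where the list did not pass (adjusted p = 0.784). It also failed with an estimated correlation (0.788), with fry (0.486), with the widest-spread probe per gene (0.204) and without replicate 7, 8 or 9. By limma 0 were called over all genes or adjusted over the list alone, with 5 higher and 3 lower at an unadjusted p below 0.05. The members with the smallest p went against the list, as Rpl10a stood at -0.78 ± 0.76 (SD, n = 12) and Rps16 at -0.40 ± 0.44 (SD, n = 14).

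The recognition and engulfment genes for apoptotic cells, the function first ascribed to the receptor, had 0 of 25 members called by limma, 1 at an unadjusted p below 0.05, and an adjusted p of 0.628. Itgb5 stood at -0.40 ± 0.65 (SD, n = 14) and Bcar1 at -0.61 ± 1.11 (SD, n = 13), neither past the threshold. The 29 measured neighbours of the Jmjd6 gene had 0 called members, 0 at an unadjusted p below 0.05, a mean of -0.039 and an adjusted p of 0.692. The splicing genes lay at a mean of 0.007 over 57 members (adjusted p = 0.881). Histone and chromatin genes had 0 of 90 members called (adjusted p = 0.881), with 1 lower and 1 higher at an unadjusted p below 0.05. The adipocyte list held Lpl as its 1 called member among 16, at a gene mean of -1.02 ± 0.46 (SD, n = 14), and did not pass (adjusted p = 0.349). Collagens and other structural matrix genes had 0 of 43 members called (adjusted p = 0.344), with 6 lower and 2 higher at an unadjusted p below 0.05. Among them was Dcn at -0.65 ± 0.72 (SD, n = 14). Cell cycle genes had 0 of 56 called over all genes and 1 adjusted over the list alone, Cdca8, at -0.91 ± 0.68 (SD, n = 12). Igf2, in the imprinted and growth factor lists, stood at 0.67 ± 0.68 (SD, n = 14) and was above 0 on 13 of 14 arrays, with values from -0.43 to 1.97 and an adjusted p of 0.588. The remaining lists had adjusted p between 0.144 and 0.950.

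The dye term was tested in the same model, and turning the Cy3 arrays once more gives this same test. It was called for 1 probe, Nr4a3, an immediate early nuclear receptor gene, whose mean was -1.34 ± 0.56 (SD, n = 6) with the knockout in Cy5 and 2.01 ± 0.88 (SD, n = 7) with the knockout in Cy3 (limma, adjusted p = 0.0222). The count was 0 without any 1 of 10 of the arrays, 3 without replicate 14, and 0 with the block of number range and dye. At an unadjusted p below 0.05, 1417 probes had a dye effect.

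The arrays differed among themselves beyond the knockout. Over the 2677 best measured probes, rank correlations between arrays of the same dye ran from -0.234 to 0.544, and those between arrays of opposite dye from -0.103 to 0.253. These are correlations across probes, which are not independent replicates. The highest values joined replicates 7 and 8 (0.544), 11 and 12 (0.486), 3 and 4 (0.430) and 5 and 6 (0.415).

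**Figure D3:**
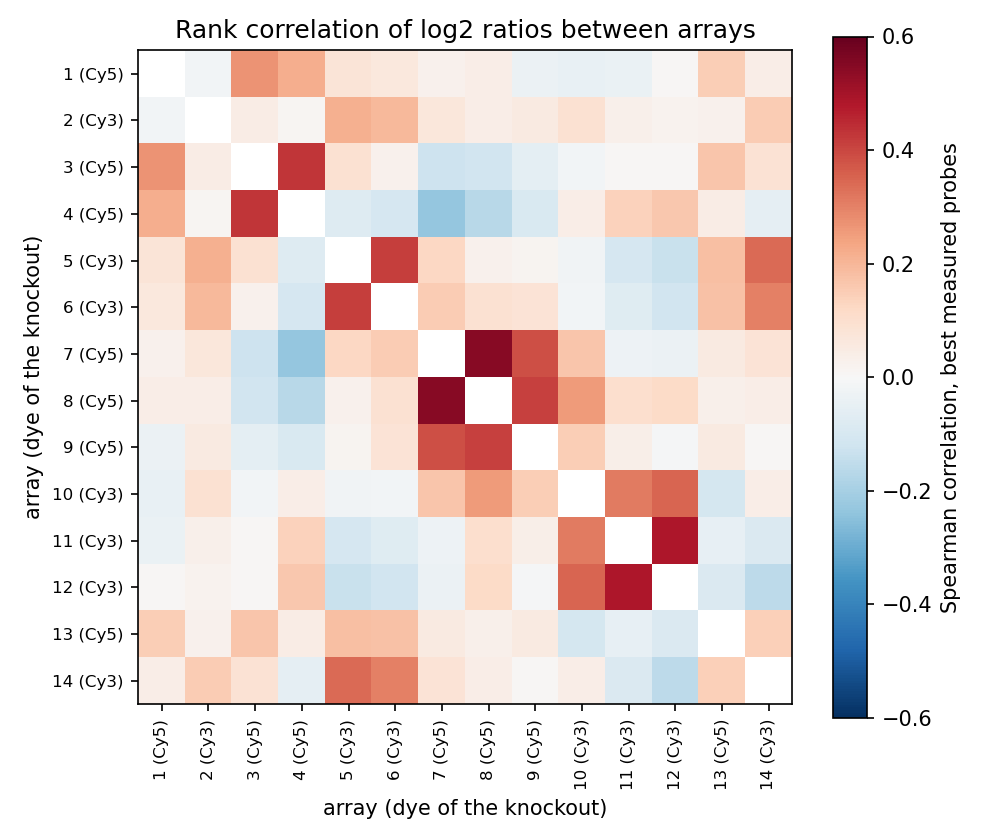
Spearman correlation of the log2 ratios between each pair of the 14 arrays, over the 2677 best measured probes, with the replicate number and the dye of the knockout on both axes and colour for the correlation. The highest value is 0.544, between replicates 7 and 8, and the lowest is -0.234.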

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

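The tests of dye bias, of unturned arrays, of macrophages, of a strain variant and of whole number ranges were chosen after the results had been seen, and the counts over other single-array sign patterns and splits were planned before those counts were seen. The Nr4a3 ratio differed between the dye orientations, with a dye term of -1.67 (limma, adjusted p = 0.0222), which is the dye result given above. Of 100 drawn splits of the arrays into 7 and 7, 3 called as many probes, the real one included, and the highest other split also called 1. That share holds only for exchangeable arrays, which these were not, so chance is not excluded. At an unadjusted p, 10 of the 100 splits gave as many dye probes, and the highest other split gave 2815 against 1417, which points to structure among the arrays that the dye does not account for.

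The 6 called probes were compared with 100 drawn sign patterns of whole arrays out of 8192. Only the real pattern, 1 of 100, called as many probes, also at 1.5-fold, and the highest other pattern called 1 where the real one called 6. It was likewise 1 of 100 for the 4 called lists, against at most 3 in another pattern. However, 28 other patterns called at least 1 list, so the adjusted p of the preset list test overstates the evidence for a called list. Chance is excluded by these counts only for exchangeable arrays, and these were not exchangeable, as pairs of the same dye within replicates 1 to 6 and 7 to 12 had a median rank correlation of 0.368 over the best measured probes, against 0.004 for other pairs of the same dye. Turning whole ranges of replicate numbers leaves 4 sign patterns, too few for a share below 5%: the real one called 6 probes and the highest other 3 (1 of 4 reached 6), and for lists 4 and 5 (3 of 4 reached 4). A difference between cultures unrelated to Ptdsr could not be tested, since no label ties an array to a culture, and it cannot be told apart from a knockout effect.

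The lower interferon and antigen presentation genes were weighed against technical explanations. Only 1 of 100 sign patterns, the real one, gave the list so small an adjusted p. However, this list had the smallest p of the 31 under the real pattern. Other patterns were scored on it and not on their own best list, which favours the real one. Also, 10 others called it and the smallest of these was 1.96e-06, so the preset p of 5.42e-10 overstates the evidence. A dye bias is argued against by list means of -0.344 ± 0.044 (SE, n = 7) with the knockout in Cy5 and -0.335 ± 0.114 (SE, n = 7) in Cy3, if the arrays had been turned before deposit. Swapped arrays that had not been turned cannot be told apart from a knockout effect, since 1417 probes had a dye term and 935 a mean ratio at an unadjusted p below 0.05, and 2 of 100 sign patterns but 10 of 100 splits gave 1417 or more. Fewer macrophages cannot be told apart from a change in the fibroblasts. The 7 well measured markers averaged -0.385 ± 0.240 (SE between genes), and -0.180 without the called Lyz2. Of the 7, 3 lay above 0 (Mrc1 0.004, Cybb 0.126 and H2-Eb1 0.239), each by less than its own standard error. Lyz2 (-1.62), Tyrobp (-0.65) and Cd68 (-0.52) lay below 0 by more than theirs, and Fcer1g (-0.28) by less. Only Lyz2 among them was called. A strain or probe variant acting only on genes within the histocompatibility complex would not account for the 25 members outside it (mean -0.267, 2 called). Strain differences elsewhere, or acting from the complex on other genes, were not tested. For the 5 members inside the complex a variant stays open, while 67 other genes lying between those averaged -0.00075.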

How the results depend on the processing

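Settings concerning direction, coded extremes, dim spots, position, arrays 1 and 2 and blocks of replicate numbers were added after seeing the data. Each log2 ratio already pairs both RNAs on 1 array, and no second group exists to pair arrays with. The ranges of replicate numbers used as blocks are a hint from the data, not labelled. The count of 6 probes became 11 with values required on all 14 arrays, 11 with array quality weights, 11 without ratios of small whole numbers, 12 with few such ratios and 12 with robust eBayes trended on their share, with 1 higher (Cd24a) in each and 2 (also Parm1) with few such ratios. Number ranges gave 10 as a random block and 16 as a fixed block (1 and 2 higher, also at 1.5-fold), and range and dye together gave 4, all lower. The random block by range had a consensus correlation of -0.021, so it took up none of the likeness between same-dye arrays of a range. It became 0 with robust and trended eBayes and in either dye orientation alone (fewer arrays), and 1 with the Cy3 arrays turned once more. That setting exchanges the mean and the dye term, so its 1 probe, Nr4a3, is the dye-effect probe of the main model. At 1.5-fold the counts were 11 with weights, 10, 11 and 11 in the dim-spot settings, 0 in the same settings as above and 1 with the Cy3 arrays turned. Dye-effect probes numbered 0 with scaled arrays, complete probes, robust and trended eBayes, the dim-spot filters, the running median, the fixed block and the block of range and dye, 9 with weights and 2 without arrays 1 and 2. Called lists fell from 4 to 2 without centring, without the dye term, with the looser filter, with robust and trended eBayes, with coded extremes kept, with the block of range and dye and with fry, and to 1 with an estimated correlation, with Cy3 arrays alone and with the Cy3 arrays turned once more. The trend of robust and trended eBayes follows the mean log2 ratio itself, and other causes were not tested. Leaving out single arrays gave 4 to 9 probes, the same range at 1.5-fold, 0 to 3 dye probes and 1 to 5 lists (1 without replicate 9, 5 without replicate 3). The Jmjd6 mean ran from -0.77 without replicate 2 to -0.38 without replicate 14, and from -0.81 to -0.21 over the other settings, never past the threshold. Mmp13, H2-K1, Ifi27 and Lpl were called whichever array was left out. Ifi205 lost its call without replicate 3, 4, 6, 7, 8, 9 or 13 (adjusted p up to 0.113) and Lyz2 without replicate 3, 4, 7, 8, 9, 10, 11, 12 or 13 (up to 0.126). The interferon list passed under 20 alternatives and whichever array was left out, but not with the Cy3 arrays turned once more, where none of the 4 lists passed. The 20 alternatives of each list include the setting with few ratios of small whole numbers. It filtered probes and not genes, so its list results repeat the main ones and are no separate test. The ribosomal list failed in 4 of 20 alternatives (0.784 with Cy3 arrays alone, 0.788 with an estimated correlation, 0.486 with fry, 0.204 with the widest-spread probe) and without replicate 7, 8 or 9. The cytokine list failed in 12 of 20 alternatives and without replicate 4, 7, 8, 9, 10, 11 or 12. The protease list failed in 13 of 20 and without replicate 1, 4, 5, 6, 9, 11 or 12. No signal over background is recorded, so dim spots could be judged only through the ratios.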

Other observations

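Some genes outside the called set had 1 sign on nearly all arrays, and they are given here after their values were seen. One Cd24a probe stood at 0.87 ± 0.48 (SD, n = 14) and was higher on 13 of 14 arrays, with an adjusted p of 0.0559 that fell below the threshold in 10 other settings, 1 of them a left-out array (0.0072 to 0.0434), while a second Cd24a probe stood at 0.16 ± 0.55 (SD, n = 14) and was lower on 4. The Cd24a gene mean was 0.51 ± 0.41 (SD, n = 14, adjusted p = 0.472). The tetraspanin gene Cd82 stood at -0.52 ± 0.21 (SD, n = 14), lower on 14 of 14 arrays, with an adjusted p of 0.262. Among 6134 probes with a value on every array, 18 had 1 sign throughout, 16 lower and 2 higher. The called genes Mmp13, H2-K1, Ifi27, Lpl, Ifitm3 and Psmb8 were among the 16.

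Dcn, Mmp3, Igf2 and the called genes Mmp13 and Lyz2 had values that lay far apart between arrays. For Dcn, which encodes the proteoglycan decorin, they were -1.60, -1.10, -1.41, -1.59, -1.19 and -1.04 on replicates 1 to 6 and 0.62, 0.23, 0.25, 0.00, -0.45 and -0.39 on replicates 7 to 12. Replicates 13 and 14 had -0.83 and -0.63. For Mmp3 they were -0.88, -1.05, -0.71, -1.07, -0.24 and -0.48 on replicates 1 to 6, -2.78, -3.61, -1.46, -4.84, -2.78 and -4.05 on replicates 7 to 12, and -0.24 and -0.74 on replicates 13 and 14. For Igf2 they were 0.58, 0.17, 0.23, -0.43, 0.06 and 0.34, then 1.97, 1.75, 0.90, 1.21, 1.30 and 0.63, then 0.49 and 0.20, in the same order. For Mmp13 they were -1.31, -1.54, -1.45, -1.36, -1.15 and -1.11, then -2.26, -2.43, -1.66, -2.49, -1.41 and -2.78, then -0.97 and -1.08. The called Lyz2 probe had -1.11, -0.47, -0.75 and -0.91 on replicates 3 to 6, -1.39, -1.61, -1.72, -2.18, -3.04 and -2.62 on replicates 7 to 12, and -0.79 and -1.07 on replicates 13 and 14. It had no value on replicates 1 and 2. The second Lyz2 probe had -2.03, -3.80, -0.62, -1.82, -0.92 and 0.02 on replicates 1 to 6. On replicates 7 to 12 it ran from -2.54 to -1.38, and on replicates 13 and 14 it had -0.32 and -0.47. That probe did not separate replicates 1 to 6 from 7 to 12. No label assigns arrays to cultures, so no difference between arrays was tested, and the means given above pool them.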
